A study of Mus musculus with 12 samples.

How the data were processed

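Gene expression was measured in aortic vessel tissue of 12 female CD-1 mice, an outbred stock, with 1 Affymetrix mouse gene array per mouse. Per the labels' protocols, 6 mice received CM-695 by intraperitoneal injection at 80 mg/kg, given 2 h and again 1 h before sacrifice, and 6 mice received saline vehicle. CM-695 inhibits both histone deacetylase 6 (HDAC6), a mainly cytoplasmic deacetylase, and phosphodiesterase 9 (PDE9), which degrades cyclic GMP. The series design records a single vehicle injection, while the treatment protocol does not say how often vehicle was given, so the number of injections may have differed between the groups. The mice were perfused with buffered saline, the vessel was frozen, and RNA was extracted with TRIzol. Each array came from a separate animal, so the spread between arrays holds both biological and technical variation. The time of day of tissue collection, the cage and the order of dissection and hybridisation are not given in the sources used here.

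The deposited table held log2 expression values, 1 per probe set and array, for 41345 probe sets on 12 arrays. Per the submitters' processing notes, the authors made these values with RMA, which corrects background, normalizes across arrays and summarizes the probes of a probe set. The software and version that ran it are not given in the sources used here. Array medians lay between 4.69 and 4.74, and correlations between arrays across all probe sets between 0.957 and 0.977. The values carry no detection calls, so a low value does not separate weak expression from none. For arrays the number of mice, 6 per group, limits the precision.

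Probe sets were named from the platform annotation. It gave 1 gene symbol for 23521 probe sets, several for 1814 and none for 16010; the last are unnamed here, not without a gene. A current mouse gene table matched 23328 of the single-symbol probe sets by gene identifier and changed 0 symbols. Where a gene had several probe sets (1082 of 22180 genes), the 1 with the highest mean over all 12 arrays stood for it. No gene was named from a probe set with several symbols. Some probe sets repeat each other, and 802 had values identical to those of another.

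The comparison was CM-695 minus vehicle. Each probe set was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, intercept and group, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over all probe sets, with a threshold of 0.05 and no fold threshold. Differences are on the log2 scale and carry limma's standard error (SE); group values are means with SD over 6 mice. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 37 lists: 21 gene programmes and 16 sets of cell type markers. Another list, erythroid markers, had fewer than 3 measured genes and was not tested. Together the lists held 662 genes, of which 599 were measured. Beside each camera result stand camera with a correlation estimated from the arrays, and an exact two-sided permutation test of the mean of the list per mouse over all 924 assignments of 6 mice to a group, in which the smallest p that can be reached is 0.0021645. Both are adjusted over the same 37 lists. Per list, counts of members past the threshold are given over all probe sets and adjusted over the list alone.

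The groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the 15 genes with the largest rise and the 15 with the largest fall among genes past the threshold, Hspa1a, Hspa1b, Hdac6 and Pde9a, and up to 4 members of each list with the smallest p. After the values had been seen, 4 members were taken from lists past the camera threshold and 2 from the others. Predicted genes, clone names and small RNAs were counted and not named. Any other gene is said to have been chosen after its values were seen.

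On simulated values for 41345 probe sets with the spread of these arrays and 50 changed probe sets per size, the procedure recovered 48% of 1.5-fold, 94% of 2-fold, 100% of 4-fold and 100% of 8-fold changes, and 13 of its 184 calls were false. These shares are averages over randomly drawn genes with independent, normal noise. The 184 calls exceed the 64 of the real comparison, and more calls loosen the adjustment. Recovery in the real data can thus be lower, and Hspa1a, at 3.66-fold, did not pass there. On simulated lists of 20 genes over 22180 genes it recovered 10 of 10 changed lists and called 0 of 190 unchanged lists. Those genes were simulated as independent, so this check says nothing about lists whose genes vary together.

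Alternatives fixed at the start were the replicate number as a block, a filter on dim probe sets, a repeated quantile normalization, centring on array medians, array quality weights, eBayes with trend and robust, an adipocyte marker score as covariate, leaving out each mouse in turn, a log odds criterion, a 1.5-fold threshold, probe sets with 1 symbol alone, the mean of a gene's probe sets, and the other list tests. Added after the data had been seen were a cardiac marker score as covariate, leaving out the 2 arrays of lowest quality weight, and counting identical probe sets once. Matplotlib 3.10.9 drew the figures.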

Results

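The data set compared aortic tissue of 6 mice given CM-695, an inhibitor of HDAC6 and PDE9, with that of 6 mice given saline, about 2 h after the first dose. RNA of each mouse was measured on its own array as RMA log2 values. Arrays of both groups had similar distributions, and the first principal components held 17.6% and 12.7% of the variance. The series title concerns heat shock protein 70 and thrombosis, so the HSP70 genes were examined first, then all probe sets, then gene programmes and cell type markers.

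Transcripts of the stress-inducible HSP70 chaperones were higher in every CM-695 aorta than in any vehicle aorta. Hspa1a measured 6.60 ± 0.87 (SD, n = 6) after CM-695 and 4.72 ± 0.46 (SD, n = 6) after vehicle, a difference of 1.87 on the log2 scale (SE 0.35) or 3.66-fold. Hspa1b measured 7.79 ± 0.92 against 6.25 ± 0.38 (SD, n = 6 each), a difference of 1.54 (SE 0.36) or 2.90-fold. The co-chaperone gene Hsph1, an HSP70 nucleotide exchange factor, differed by 0.97 (SE 0.22), again with 6 of 6 treated mice above all vehicle mice, and Stip1, which links HSP70 to HSP90, by 0.56 (SE 0.13). Across all probe sets these differences did not pass the threshold (limma adjusted p = 0.0647 for Hspa1a, 0.141 for Hspa1b, 0.136 for Hsph1 and 0.153 for Stip1). CM-695 mice 2 and 4 stood highest, at 7.72 and 7.64 for Hspa1a (the other 4 treated mice 5.77 to 6.35) and 8.95 and 8.90 for Hspa1b (6.87 to 7.63). Without both, left out after their values were seen, the differences were 1.33 (SE 0.23, adjusted p = 0.0594) and 0.97 (SE 0.21, adjusted p = 0.142). Hspa1a and Hspa1b are near-identical genes whose probe sets can share signal, so their separate values are uncertain.

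As a group the heat shock genes rose. The 25 measured members had a median difference of 0.29 log2, with 20 above 0 and 5 below, and 0 passed the threshold over all probe sets, 13 having an unadjusted p under 0.05. Adjusted over the list alone, 11 were higher, among them Hspa1a (adjusted p = 0.00345), Hsph1, Hspa1b and Stip1 (0.00621 each), and 0 lower. The small heat shock gene Cryab, chosen after its values were seen, differed by -0.65 (SE 0.28, adjusted p = 0.507 over all probe sets). The list passed camera (adjusted p = 1.00e-07), with adjusted p = 0.191 with an estimated correlation. Its mean per mouse was 7.32 ± 0.20 after CM-695 and 7.00 ± 0.067 after vehicle (SD, n = 6 each), with 6 of 6 treated mice above the highest vehicle mouse (exact permutation test, adjusted p = 0.0200).

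Neither named target of CM-695 differed detectably in transcript level. Hdac6 measured 6.14 ± 0.11 after CM-695 and 6.13 ± 0.28 after vehicle (SD, n = 6 each), a difference of 0.01 (SE 0.12, 95% confidence interval -0.26 to 0.28, limma adjusted p = 0.987). Pde9a differed by -0.15 (SE 0.11, 95% confidence interval -0.38 to 0.08, adjusted p = 0.716).

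**Figure D1:**
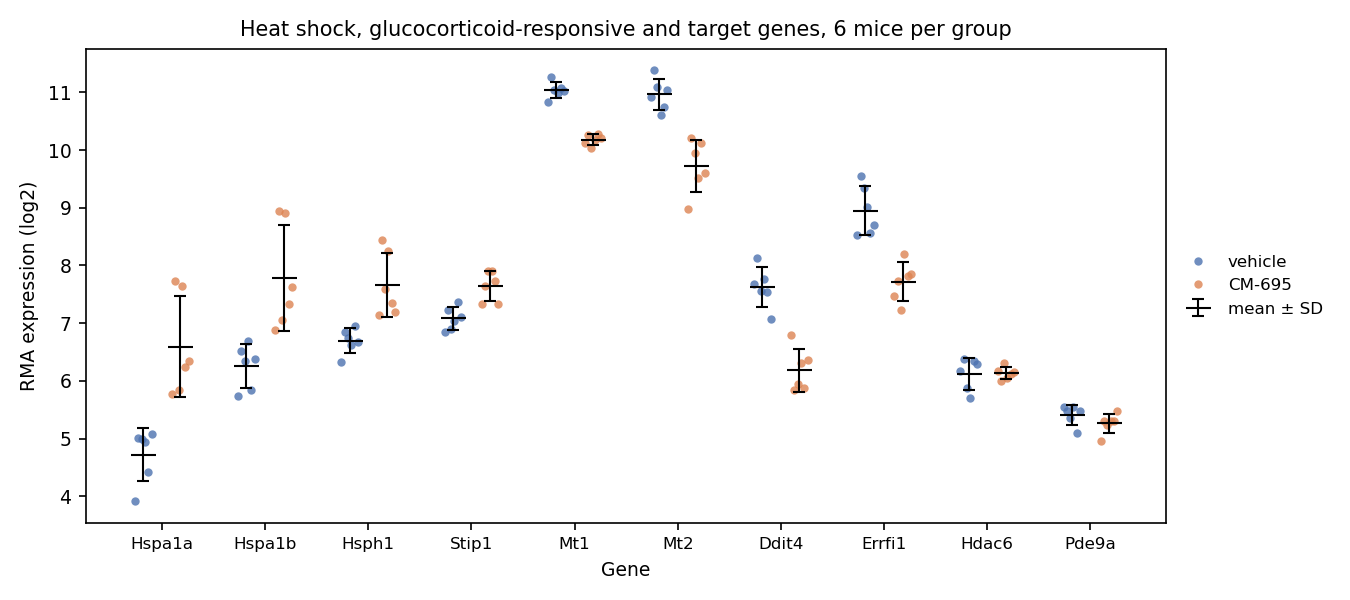
RMA expression (log2) of heat shock genes, glucocorticoid-responsive genes and the target genes Hdac6 and Pde9a in each of 6 vehicle and 6 CM-695 mice. Points are mice and bars are mean ± SD; Hspa1a, Hspa1b and Hsph1 lie above the vehicle range, and Mt1, Mt2, Ddit4 and Errfi1 below it, in 6 of 6 treated mice.

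Over all probe sets the strongest differences included many genes of the circadian clock, and most were lower after CM-695. Of 41345 probe sets, 64 passed the threshold, 10 higher and 54 lower, and 3774 had an unadjusted p under 0.05. The 64 held 60 distinct sets of values and covered 37 genes, 5 higher and 32 lower, each measured by a probe set with a single symbol; 18 probe sets were unnamed and 8 named several genes. The 5 genes that rose were the clock activators Arntl and Npas2, the thyrotropin receptor gene Tshr (1.66, SE 0.20), Dtx4 (0.78, SE 0.10) and the retinaldehyde reductase gene Dhrs3 (0.62, SE 0.098). Among named genes past the threshold and outside the clock, the largest falls were in Mfsd2a, a lysophospholipid transporter (-2.75, SE 0.39), Tcap, a sarcomere protein of striated muscle (-2.07, SE 0.18), the nuclear receptor gene Nr4a3 (-1.61, SE 0.27), Ddit4 (-1.44, SE 0.19) and Slc25a33, a mitochondrial pyrimidine nucleotide carrier (-1.29, SE 0.21). The dipeptidase gene Dpep2 fell by 1.27 (SE 0.18). Tcap (adjusted p = 0.000174) measured 6.45 ± 0.37 after CM-695 and 8.52 ± 0.28 after vehicle (SD, n = 6 each). Markers of heart muscle, measured as a list, had a median difference of -1.60 log2 in the same mice. All 20 genes named for the size of their change lay beyond the vehicle range in 6 of 6 treated mice. They were chosen as genes past the threshold in these same mice, so this separation follows largely from the choice.

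Among 22180 genes, 98 had every CM-695 mouse above every vehicle mouse and 141 had every one below, together 1.08% of genes against 0.216% by chance. The number of probe sets past the threshold depended on single mice. It was 33, 29, 26, 33, 54 and 31 without vehicle mouse 1 to 6 in that order, and 31, 98, 24, 38, 22 and 32 without CM-695 mouse 1 to 6. Of 25 named genes past the threshold, 17 stayed past it without any 1 mouse; Dhrs3, Slc25a33, Sgk1, Nr4a3, Mt2, Errfi1, Mfsd2a and Dpep2 did not, with adjusted p up to 0.0914. With the cardiac marker score as a covariate, an alternative chosen after the data had been seen, 13 probe sets passed; named genes that no longer passed had 0.767 to 1.17 times their difference, so these losses do not show a cardiac origin.

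Genes of the circadian clock moved in both directions. Arntl, which encodes the clock activator BMAL1, rose from 4.59 ± 0.28 after vehicle to 7.29 ± 0.24 after CM-695 (SD, n = 6 each), a difference of 2.69 (SE 0.15, adjusted p = 2.80e-06) or 6.48-fold, and Npas2, a paralogue of Clock that pairs with BMAL1, rose by 2.24 (SE 0.24, adjusted p = 0.00139). Dbp, a direct target of the activator, fell from 9.04 ± 0.38 to 6.35 ± 0.16 (SD, n = 6 each), a difference of -2.68 (SE 0.16, adjusted p = 5.15e-06) or 6.43-fold. The related transcription factor gene Tef fell by 1.59 (SE 0.12), the period gene Per3 by 1.86 (SE 0.14), the repressor genes Ciart and Bhlhe41 by 1.59 (SE 0.15) and 1.57 (SE 0.16), the deubiquitinase gene Usp2 by 1.69 (SE 0.20), and Nr1d2, which encodes REV-ERB beta, by 1.42 (SE 0.17). Per1 fell by 0.99 (SE 0.13), and the clock-controlled kinase gene Wee1, chosen after its values were seen, by 1.05 (SE 0.14).

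Of 18 measured clock genes, 2 rose and 9 fell over all probe sets. Adjusted over the list alone, 5 were higher and 11 lower. The list median was -0.80 log2 (camera adjusted p = 1.23e-10, adjusted p = 0.0151 with an estimated correlation). Its mean per mouse was lower in 6 of 6 treated mice than in any vehicle mouse (exact permutation test, adjusted p = 0.0200). All 11 clock genes past the threshold stayed past it without any 1 mouse. Among the others, Clock (0.50, SE 0.097) and Nr1d1, which encodes REV-ERB alpha (-0.16, SE 0.15), did not pass over all probe sets. Nor did the repressor genes Cry1 (0.46, SE 0.14), Nfil3 (0.54, SE 0.12) and Cry2 (-0.46, SE 0.16). Cry1 and Nfil3 were among the 5 higher over the list alone, so the directions did not divide activators from repressors. All of these genes were chosen after their values were seen.

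**Figure D2:**
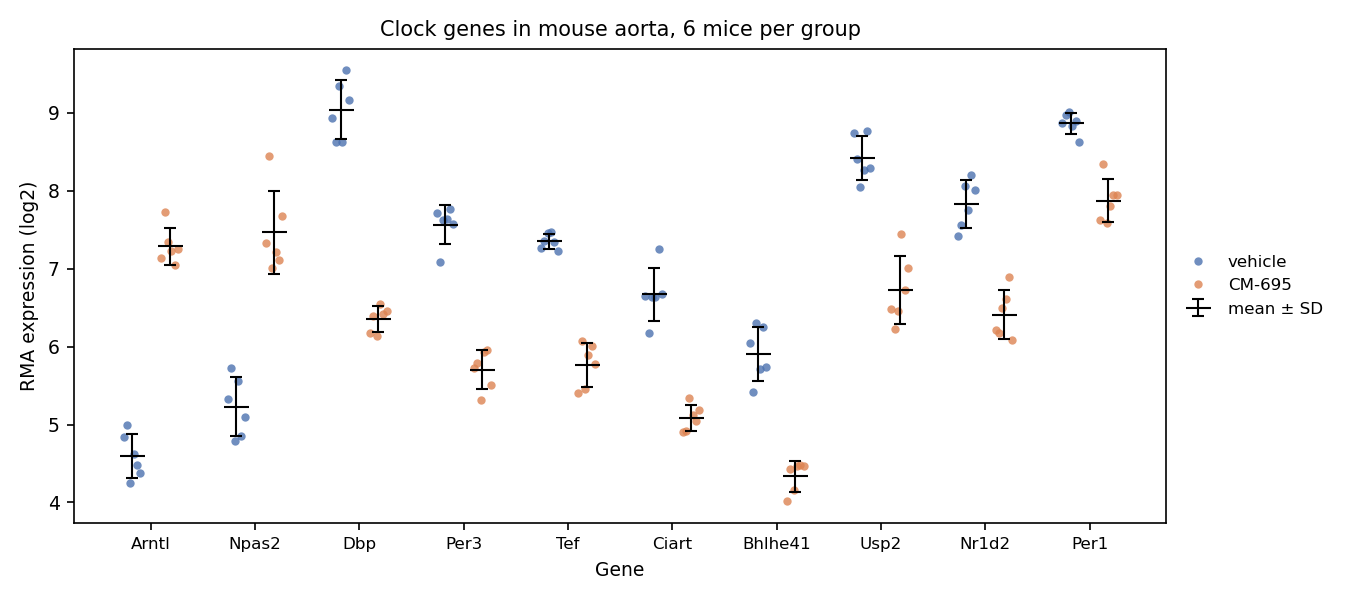
RMA expression (log2) of clock genes in each of 6 vehicle and 6 CM-695 mice, with points for mice and bars for mean ± SD. Arntl and Npas2 were higher and the other 8 genes lower in 6 of 6 CM-695 mice than in any vehicle mouse.

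Genes induced by glucocorticoids were lower after CM-695. The metallothionein genes Mt1 and Mt2, which bind zinc and copper, fell by 0.85 (SE 0.087, adjusted p = 0.000986) and 1.24 (SE 0.20, adjusted p = 0.0341), the mTORC1 inhibitor gene Ddit4 by 1.44 (SE 0.19), the EGFR inhibitor gene Errfi1 by 1.23 (SE 0.20), and the NF-kB inhibitor gene Nfkbia by 0.91 (SE 0.11). The kinase gene Sgk1, chosen after its values were seen, fell by 0.87 (SE 0.14, adjusted p = 0.0341). Of 21 measured members of this list, 7 fell over all probe sets, Per1 among them, and 0 rose. Adjusted over the list alone, 12 were lower and 1 higher; the latter was Angptl4, an inhibitor of lipoprotein lipase also induced by fatty acids, at 1.09 (SE 0.26). Fkbp5, a co-chaperone of the glucocorticoid receptor, differed by -1.47 (SE 0.27, adjusted p = 0.0550 over all probe sets); Angptl4 and Fkbp5 were chosen after their values were seen. The list median was -0.57 log2 (camera adjusted p = 3.50e-15, adjusted p = 0.0295 with an estimated correlation), and the mean per mouse was lower in 6 of 6 treated mice (exact permutation test, adjusted p = 0.0200). Of the 21 genes, 6 also belonged to another list, Per1 to the clock list. The cause of these falls was not tested. Collection times are not given and the number of injections may have differed, so neither can be told apart from CM-695.

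Sterol synthesis genes rose as a group. Fdps, which makes farnesyl diphosphate, differed by 0.98 (SE 0.25), Sqle, squalene epoxidase, by 0.81 (SE 0.21), Dhcr7, the last reductase of cholesterol synthesis, by 0.77 (SE 0.18) and Mvd, mevalonate diphosphate decarboxylase, by 0.43 (SE 0.11). Of 16 measured members, 0 passed over all probe sets, 10 had an unadjusted p under 0.05, and 9 were higher adjusted over the list alone. The list median was 0.53 log2 (camera adjusted p = 2.17e-08, adjusted p = 0.286 with an estimated correlation). Its mean per mouse was higher in 6 of 6 treated mice than in any vehicle mouse (exact permutation test, adjusted p = 0.0200), and CM-695 mouse 3 stood highest at 8.17, the other treated mice lying between 7.38 and 7.56.

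Matrix and immediate early genes were lower by camera alone. The 25 measured genes of the extracellular matrix and elastic fibre had a median of -0.32 log2 (camera adjusted p = 7.54e-07, adjusted p = 0.708 with an estimated correlation), with 22 below 0; Vcan, which encodes versican, differed by -0.71 (SE 0.23), the gelatinase gene Mmp2 by -0.51 (SE 0.16), Timp3 by -0.48 (SE 0.19) and Sparc by -0.36 (SE 0.15). With 1 mouse left out the matrix median ran from -0.53 to -0.25. Among treated mice, mouse 2 was highest and mouse 3 lowest for the matrix mean (8.87 and 7.64), as for the smooth muscle mean (10.4 and 8.30). No matrix gene passed over all probe sets or adjusted over the list alone, and 6 had an unadjusted p under 0.05. The exact permutation test of the matrix mean per mouse gave adjusted p = 0.509. Among 33 immediate early genes, 1 fell over all probe sets, Nr4a3, and 5 were lower adjusted over the list alone. Its relative Nr4a2 differed by -1.08 (SE 0.20, adjusted p = 0.0585), Csrnp1 by -0.64 (SE 0.12) and Fosb by -0.58 (SE 0.16). The median of this list was -0.09 log2 (camera adjusted p = 0.0160, adjusted p = 0.758 with an estimated correlation), and the exact permutation test gave adjusted p = 0.509. Leaving out vehicle mouse 2 or 3 or CM-695 mouse 3 or 5 ended the camera call for the immediate early list (adjusted p up to 0.162), and with 1 mouse left out its median ran from -0.16 to -0.00.

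**Figure D3:**
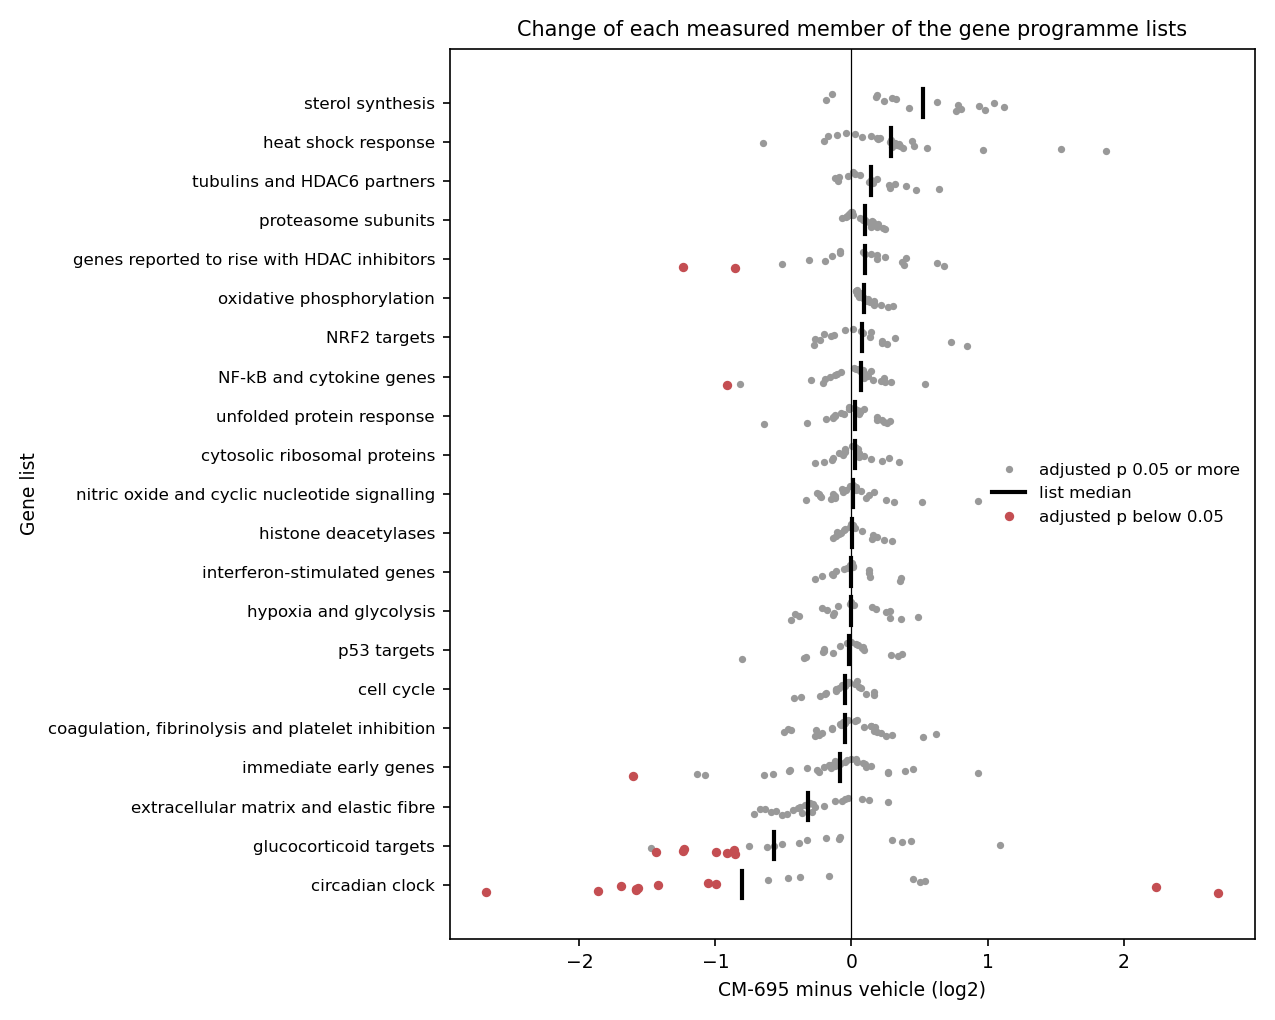
Difference between CM-695 and vehicle (log2) for each measured gene of the 21 gene programmes, with the list median as a vertical bar and genes past the threshold in red. The circadian clock (-0.80) and glucocorticoid targets (-0.57) have the lowest medians, and sterol synthesis (0.53) and the heat shock response (0.29) the highest.

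Genes closest to the series' subject of thrombosis and to the targets of the drug did not pass as lists. Coagulation, fibrinolysis and platelet inhibition genes (30 measured) had a median of -0.05 log2 (camera adjusted p = 0.931); 0 passed over all probe sets, 4 had an unadjusted p under 0.05, and 1, the plasminogen co-receptor gene Anxa2 (0.53, SE 0.11), was higher adjusted over the list alone. The tissue factor gene F3 differed by -0.26 (SE 0.12, adjusted p = 0.523). Nitric oxide and cyclic nucleotide signalling genes (27 measured) had a median of 0.01 (adjusted p = 0.957), with 0.52 (SE 0.14) for the natriuretic peptide clearance receptor gene Npr3 and 0.32 (SE 0.10) for Nos2. The 18 histone deacetylase genes had a median of 0.00 (adjusted p = 0.957), and the 17 tubulins and HDAC6 partners of 0.14 (adjusted p = 0.0642). This last list passed in 7 of 24 alternatives, among them leaving out vehicle mouse 2 or 3 or CM-695 mouse 1 (adjusted p 0.0110 to 0.559 over the 24), and its mean was above the vehicle range in 5 of 6 treated mice (exact permutation test, p = 0.0238, adjusted p = 0.147). Of 19 measured genes reported to rise with HDAC inhibitors, 0 rose and 2 fell over all probe sets, Mt1 and Mt2, which the glucocorticoid list also holds. At an unadjusted limma p under 0.05, 4 were higher and 3 lower. The median was 0.10, with 11 above 0 and 8 below, while camera pointed downward (adjusted p = 0.758). Of the 19 genes, 11 also belonged to another list. A listed H2B histone gene had no probe set of its own; of 6 probe sets naming it with other histone genes, 1, which names 12, rose by 0.52 (SE 0.084, adjusted p = 0.0341).

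Heart muscle transcripts were lower in several CM-695 samples, and this was the largest shift among the cell type markers. Actc1, cardiac actin, measured 9.25 ± 1.22 after CM-695 and 10.85 ± 0.68 after vehicle (SD, n = 6 each), the atrial light chain gene Myl7 differed by -1.89 (SE 0.50), the cardiac troponin gene Tnni3 by -1.67 (SE 0.49) and the calcium channel gene Ryr2 by -0.82 (SE 0.25). Of 11 cardiac markers, 0 passed over all probe sets, 7 had an unadjusted p under 0.05 and 7 were lower adjusted over the list alone. The list median was -1.60 log2 (camera adjusted p = 4.46e-08, adjusted p = 0.286 with an estimated correlation). The mean per mouse was 6.84 ± 0.74 after CM-695 and 7.94 ± 0.58 after vehicle (SD, n = 6 each; exact permutation test, adjusted p = 0.147), and 3 of 6 treated mice lay below the lowest vehicle mouse.

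Fibroblast markers were lower as a list (11 measured, median -0.39 log2, camera adjusted p = 7.54e-07, adjusted p = 0.286 with an estimated correlation), with 11 of 11 below 0 and Dpt, dermatopontin, at -0.53 (SE 0.18) and the collagen gene Col3a1 at -0.59 (SE 0.25). The matrix list shares 4 of these 11 genes, so the matrix and fibroblast results are not separate. Platelet markers were higher (9 measured, median 0.23, camera adjusted p = 0.0255, adjusted p = 0.633 with an estimated correlation), with Gp6, the platelet collagen receptor, at 0.41 (SE 0.14) and the chemokine gene Ppbp at 0.76 (SE 0.29). That call was lost without vehicle mouse 4, 5 or 6 or CM-695 mouse 1 or 4 (adjusted p up to 0.104). Liver markers were higher (9 measured, median 0.35, camera adjusted p = 0.00762, adjusted p = 0.722 with an estimated correlation), with Ttr, transthyretin, at 0.69 (SE 0.24). Without CM-695 mouse 5, in which the albumin gene Alb measured 10.7, the liver median was 0.0611 (adjusted p = 0.315). In the exact permutation test the adjusted p was 0.170 for fibroblast and for platelet markers and 0.509 for liver markers. Over all probe sets, 0 of these fibroblast, platelet and liver markers passed, and 3, 4 and 1 of them had an unadjusted p under 0.05. In vehicle aorta 5 of 9 platelet and 4 of 9 liver markers exceeded the array median, against 11 of 11 fibroblast markers. The other platelet and liver markers were dim, and such values do not separate weak expression from none.

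Vascular smooth muscle markers had a median of -0.27 (adjusted p = 0.0576) and passed in 10 of 24 alternatives (adjusted p 2.70e-06 to 0.939), among them leaving out vehicle mouse 1, 5 or 6 or CM-695 mouse 2 or 6. Without CM-695 mouse 2, the mouse with the highest smooth muscle mean, the median was -0.54 (adjusted p = 5.05e-06). With any 1 mouse left out the smooth muscle median ran from -0.54 to -0.12 (camera adjusted p up to 0.470). Endothelial markers had a median of 0.01 (adjusted p = 0.931), adipocyte markers 0.04 (0.700), brown adipocyte markers 0.00 (0.605), macrophage markers -0.04 (0.700) and lymphocyte markers 0.15 (0.112). Without CM-695 mouse 2 the adipocyte list (0.20, adjusted p = 0.0196) and the lymphocyte list (0.18, adjusted p = 0.0198) passed, as they did in 2 and 4 of 24 alternatives in all (adjusted p 0.0181 to 0.990 and 0.0198 to 0.722). With the cardiac marker score as a covariate Tcap differed by -1.62 (adjusted p = 0.00152), Dbp by -2.77 and Arntl by 2.83, all past the threshold, while 17 of the 25 named genes no longer passed. Of these 17, 11 had a larger difference than without the score and 6 a smaller one, and standard errors were 1.25 to 1.40 times as large; Mfsd2a, for example, went from -2.75 (SE 0.39) to -2.89 (SE 0.55), and Mt2, the most reduced, from -1.24 (SE 0.20) to -0.95 (SE 0.25).

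**Figure D4:**
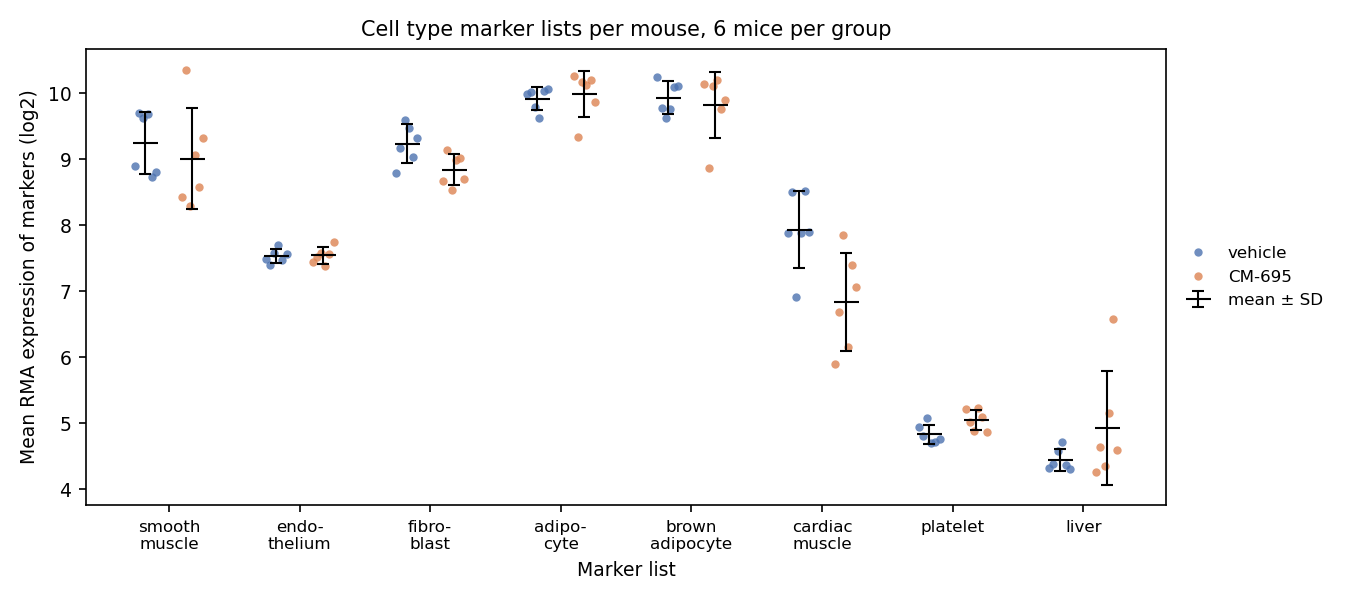
Mean RMA expression (log2) of marker genes of 8 cell types in each of 6 vehicle and 6 CM-695 mice, with points for mice and bars for mean ± SD. Cardiac markers averaged 6.84 after CM-695 and 7.94 after vehicle with overlapping ranges, and a single CM-695 mouse stood highest for liver markers at 6.58.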

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

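In 298 series of 6 values, each the mice of 1 group for a named gene or a list mean, 25 had a highest or lowest mouse far from the other 5; chance alone gives about 5% of series. Values are log2 with the range of the other 5 mice of the group in brackets.

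CM-695 mouse 3 stood apart in 7 series. It was high for the sterol enzymes Dhcr7 at 8.19 (7.07 to 7.33) and Fdps at 8.59 (7.36 to 7.60), for the sterol synthesis mean at 8.17 (7.38 to 7.56), for Pgd of the pentose phosphate pathway at 11.1 (9.70 to 10.2) and for pyruvate kinase Pkm at 11.4 (10.8 to 10.9). It was also high for the interferon-stimulated mean at 5.25 (5.13 to 5.16) and low for the vasodilator peptide gene Adm at 4.89 (5.44 to 5.65).

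CM-695 mouse 2 stood apart in 5 series and had the lowest array quality weight (0.574). Lipoprotein lipase Lpl was at 9.89 (11.0 to 11.6), the fatty acid transporter Slc27a2 at 6.13 (7.60 to 8.29), the brown adipocyte mean at 8.87 (9.76 to 10.2) and the oxidative phosphorylation mean at 9.07 (9.75 to 10.1). Hdac5 was high there at 8.06 (7.39 to 7.63). The smooth muscle mean of this mouse, 10.4, was the highest of the 12.

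In CM-695 mouse 5, the liver enzyme Cyp3a11 was at 5.24 (4.19 to 4.44) and the ribosomal stalk gene Rplp0 at 7.38 (6.92 to 7.09). The ribosomal protein mean of CM-695 mouse 4 was 7.80 (7.68 to 7.72), and the neutrophil mean of CM-695 mouse 6 was 4.09 (3.83 to 3.90).

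Among vehicle mice, Per3 was low in mouse 2 at 7.08 (7.58 to 7.76), still above all CM-695 mice, and Rplp0 was high there at 7.56 (7.27 to 7.38). Squalene epoxidase Sqle was low in mouse 1 at 5.71 (5.96 to 6.06). The platelet chemokine gene Ppbp was high in mouse 3 at 7.04 (5.71 to 6.20), and cardiac troponin Tnni3 was low there at 7.30 (8.87 to 9.57). Egfl7, an endothelial gene, was high in mouse 4 at 6.97 (6.50 to 6.65), and the nerve and Schwann cell mean was high in mouse 5 at 5.17 (4.68 to 4.85). In mouse 6 the neutrophil gene Retnlg was high at 4.17 (3.39 to 3.63) and Cyp3a11 was low at 3.76 (4.04 to 4.20).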

How the results depend on the processing

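The cardiac covariate, leaving out the 2 arrays of lowest quality weight, and counting identical probe sets once were chosen after the data had been seen; the other alternatives were planned. The 64 probe sets past the threshold became 15 with the replicate number as a block, 116 without dim probe sets, 124 with the adipocyte score, 13 with the cardiac score and 181 by log odds, and 22 to 98 with 1 mouse left out; the cause was not tested. Counts with the other 8 settings lay within 1.5 times of 64. No label says that the shared replicate numbers pair the mice. Same-number correlations ran from -0.250 to 0.205, 3 of 6 exceeded 0.1, and 1 of 6 mice correlated best with its own number. These values gave no clear sign of pairing, but 6 weak correlations cannot exclude it. Under the block, 13 of 25 named genes no longer passed, with differences unchanged, standard errors 0.772 to 1.15 times as large and fewer degrees of freedom. Among named genes that still passed, standard errors were 0.611 (Npas2) to 1.09 (Bhlhe41) times as large.

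Hspa1a passed in 3 of 22 alternatives. It was at 1.87, unchanged, without dim probe sets (adjusted p = 0.0323) and with the mean of a gene's probe sets (0.0287), and at 1.98 with the adipocyte score (0.0205). In the first 2 of these settings p was adjusted over fewer tests than the 41345 of the main analysis. The smallest differences of Hspa1a were 1.48 without the 2 arrays of lowest quality weight (0.0988) and 1.53 with the cardiac score (0.514). Over all 22 the adjusted p ran from 0.0205 to 0.514. Hspa1b passed at 1.66 with the adipocyte score (0.0394; 0.0394 to 0.644 over 22). The heat shock list kept its direction in all 24 alternatives (0.21 to 0.33) and lost its call in 1, at 0.29 with an estimated correlation (adjusted p = 0.191; 2.40e-09 to 0.191 over 24). The clock and glucocorticoid lists passed in all 24. The 5 other programmes past camera became 2 with an estimated correlation, 3 by exact permutation and 8 with the cardiac score, and the 4 cell types became 0, 0 and 3; without adjustment, 2 and 3 cell types had p under 0.05 in the first 2 tests. Cell types numbered 7 without the 2 weakest arrays, 7 without CM-695 mouse 2, and 3 to 7 with any 1 mouse left out. The platelet list lost its call with the cardiac score: its median stayed above 0 at 0.0388, and camera, which compares a list with all other genes, pointed downward (adjusted p = 0.955); the cause was not tested.

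Among single lists and named genes, 2985 values kept their side of the threshold, 120 lost it, 52 gained it, and 1, the platelet list above, lost it with the direction of its test changed. In 80 values from 17 results the sign changed while neither value passed, at sizes up to 0.233. Without detection calls, signal over background could not limit the tests.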

Other observations

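The vessel samples carried abundant brown fat transcripts in both groups: Ucp1, the thermogenic uncoupling protein gene, chosen after its values were seen, measured 12.6 ± 0.47 after CM-695 and 12.6 ± 0.23 after vehicle (SD, n = 6 each). Among stress programmes, unfolded protein response genes had a median of 0.03 log2 (camera adjusted p = 0.931), with Herpud1, which acts in the degradation of misfolded proteins, at -0.64 (SE 0.17, adjusted p = 0.214) and Chac1 at -0.33 (SE 0.096). NRF2 targets had a median of 0.08 (0.700), with Pgd at 0.85 (SE 0.29) and heme oxygenase Hmox1 at -0.28 (SE 0.099). Among them 5 were higher and 1 lower at an unadjusted limma p under 0.05. Medians were -0.02 for p53 targets (0.389), -0.01 for hypoxia and glycolysis (0.758), -0.04 for the cell cycle (0.183) and -0.00 for interferon-stimulated genes (0.909). In the NF-kB and cytokine list (median 0.07, adjusted p = 0.978), Nfkbia fell, and Il1b differed by 0.54 (SE 0.13, adjusted p = 0.171).

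Proteasome subunits had a median of 0.10 (camera adjusted p = 0.0642), oxidative phosphorylation genes 0.09 (0.183) and cytosolic ribosomal proteins 0.03 (0.931). Proteasome subunits passed in 10 of 24 alternatives (adjusted p 0.00192 to 0.939), 4 of them with 1 mouse left out, and oxidative phosphorylation in 6 (7.13e-09 to 0.976), 3 of them with 1 mouse left out, where its median ran from 0.03 to 0.26; both passed with the cardiac score (0.16 and 0.23). Of the remaining cell type markers, medians were 0.02 for neutrophils (0.978), 0.09 for thymocytes (0.464), 0.11 for skeletal muscle (0.464), 0.13 for nerve and Schwann cells (0.758), 0.13 for mast cells (0.700) and 0.04 for mesothelium (0.700). Of the 64 probe sets past the threshold, 7 named the same predicted gene, alone or with others, and all 7 were lower.

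The tests of clock phase, of the dosing interval, of 2 treated mice and of both cardiac explanations were chosen only after the result was seen; the other tests were written before their own values were computed, though after the clock and heat shock differences were known.

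Clock genes. Tissue composition, as far as cardiac, smooth muscle and brown adipocyte scores measure it, is argued against as the whole cause. With these scores in the model, the median size of the change of the 11 clock genes was 1.65, against 1.59 without them. All 11 of 11 had the same sign. Fibroblast, platelet and liver scores were not in the model, so composition in those respects was not tested. In that model 5 of 11 passed the threshold, standard errors were larger for 11 of 11 and fewer degrees of freedom were left. Of the 6 that no longer passed, 3 had a larger difference, such as Nr1d2 (-1.42, SE 0.17, to -1.65, SE 0.27, adjusted p = 0.152), and 3 a smaller one, Usp2 most (-1.69, SE 0.20, to -1.28, SE 0.24, adjusted p = 0.217). A different clock phase at tissue collection may be involved. The sign predicted by their arm of the clock was found for 11 of 11 genes past the threshold, and for 18 of 18 measured ones. This count takes the repressor genes Cry1 and Nfil3, both higher, with Arntl. It also holds small differences such as that of Nr1d1 (-0.16, SE 0.15), and the test was written after the signs were seen. Phase cannot be told apart from a clock response to CM-695, because collection times are not given in the sources used here. A response within the dosing interval, by decay alone in 2 h, would need a half-life of Dbp transcripts of 0.745 h or less. That value takes transcription to have stopped fully at the first dose, and no half-life was measured here. The bound that leaves this open, 0.1 to 2 h, was set after that value was seen. Decay covers falls only and cannot give the rises of Arntl (2.69) and Npas2 (2.24).

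Heat shock genes. With the same 3 scores in the model the list median was 0.34, against 0.29 without them. This argues against tissue composition, as far as these 3 scores measure it, as the whole cause. CM-695 mice 2 and 4, the highest at 7.56 and 7.57, carried part of the difference, as the difference in list means went from 0.33 to 0.20 without both; that they carried all of it is argued against, since the list median was then 0.26, against 0.29 (camera adjusted p = 0.000497). A difference in handling, the number of injections included, or in clock phase stays open: after removing group means, heat shock and clock scores correlated at r = -0.103 over 12 mice (permutation p = 0.743; rho = -0.0699, permutation p = 0.831; r = -0.285 without the 2 farthest mice). Within groups of 6, r was 0.214 for vehicle (exact p = 0.683; rho = 0.543, exact p = 0.297; r = -0.409 without 2 mice) and -0.282 for CM-695 (exact p = 0.525; rho = -0.486, exact p = 0.356; r = 0.211 without 2 mice), with adjusted p of 0.533 or more over these 3 relations.

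Cardiac markers. Heart tissue carried along in dissection is a possible explanation that the test below cannot decide. After removing group means the 11 markers varied together, with a mean pairwise r of 0.552 across genes. This was above the 99th percentile (0.244) of 10000 random lists of matched expression. Markers of 1 cell type can vary together whatever the cause. The same measure was 0.803 for smooth muscle and 0.758 for liver markers, and 0.202 for endothelial ones. None of the 11 belonged to another list, and 9 exceeded the array median in vehicle aorta. A response to CM-695 stays open, as 3 of 6 treated mice lay within or above the vehicle range. The first bound written for that test, 3 mice, would have counted against a response; it was raised to 5 after the value was seen, because carry-over varies between mice.

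Regrouping the mice tested chance, on 100 of the 462 splits into 6 and 6. For the 64 probe sets, 1 split, the real one, gave as many, and the highest other gave 4; for the heat shock median of 0.29, 1 split, again the real one, gave as much, and the highest other gave 0.22. Random assignment of mice was therefore made unlikely for both but not excluded, as 100 splits cannot show a share below 1 in 100. For the number of other programmes past camera (5), 41 of 100 splits gave as many, with a highest of 9. For the number of cell types (4), 57 of 100 did, with a highest of 11. Counts of that size thus arose by regrouping alone.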
